A study of Mus musculus with 13 samples.

How the data were processed

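Total RNA was taken from whole kidney of 13 mice and sequenced, 1 library per mouse. Per the labels' protocols, RNA was extracted with RNAiso Plus, its integrity was checked on an Agilent instrument, it was purified with RNAClean XP beads and DNase, and libraries followed a standard Illumina protocol. Whether the library kit marked strand, the tool that counted reads, the time between injection and sampling, the sex of the mice and any sequencing batch were not given in the sources used here. Mice were placed in 4 groups by genotype and treatment as the labels state them: wild type with saline (3), knockout with saline (3), wild type with LPS (4) and knockout with LPS (3). Each label number was taken as a separate mouse.

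The authors deposited 1 table of 34745 genes with raw counts and FPKM for each library, in 26 columns matched to the samples by their names. Per the file headers, the count columns hold counts per gene, and their values were whole numbers with a different total in each library. Per the file headers, the other columns hold FPKM, counts per kilobase of gene model, scaled to the library's total count. Dividing counts by FPKM and by the library's total gave the same gene length in every library within 0.0833%, with a median of 3745 bases, so the FPKM carried no information beyond the counts and were not tested. The submitters' processing notes name TopHat2 2.0.9, TopHat, HISAT2 and edgeR without saying what each was used for. They also name the human build hg38. The gene identifiers in the table are Ensembl mouse identifiers on mouse chromosomes, and 34344 of them were found in the GENCODE M21 annotation of GRCm38. All of those lay on the same chromosome as in that annotation, and 80.9% had the same start and end, so the coordinates were read as GRCm38. No strand setting of the counting is known, so antisense and overlapping genes, and near-identical paralogs such as Saa1 and Saa2, are uncertain.

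Counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16. No count was recorded in any library for 12192 genes. filterByExpr with a minimum count of 10 kept 15703 genes, which held at least 99.928% of the counts of each library. Libraries held 14372212 to 17668334 counts and were scaled by TMM factors of 0.7724 to 1.193. A quasi-likelihood model with a mean for each of the 4 groups was fitted to all 13 libraries at once. From it 5 comparisons were taken, LPS against saline in each genotype, knockout against wild type with LPS and with saline, and the difference of the LPS responses between genotypes (interaction). P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM with TMM factors. Where a group had 0 counts of a gene, 3 counts over that group were taken as the floor and the fold given as a bound, and intervals and floors cover counting error only. Principal components were taken from log2 CPM with a prior count of 2.

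The design, the comparisons, the 34 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists cover pathways and markers of kidney, immune and neighbouring cell types, and each was tested with camera from limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. camera with an estimated correlation and fry were run as alternatives. Values printed for lists are those with the estimated correlation unless stated. Where 26 tested identifiers shared a symbol, the one with the highest mean stood for it in the lists. Named genes are, per comparison, up to 8 of the largest rises and falls among called genes whose libraries did not overlap between the groups, with a mean of at least 5 CPM over the 13 libraries. Predicted genes, pseudogenes, identifiers without a symbol and immunoglobulin or T-cell receptor segments were passed over, and the overlap rule was not used for the interaction. Further named genes are up to 4 called members of each list with the smallest p, or up to 2 with the highest mean where none was called. Gstk1, Havcr1, Lcn2, Tnf, Il1b, Il6, Ccl2, Nos2, Arg1, Mrc1, Cd86, Adgre1, Fos, Jun, Junb, Fosl1, Nfkb1, Rela, Nfkbia, Adipoq and Nnt could be named in any comparison.

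Replicates were compared over genes with at least 20 summed counts. The chi-square per degree of freedom of pairs within a group was 12.47 to 121.5, far above counting noise, so no library was counted as deposited again under another name. The alternatives were RLE factors, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in at least 3 libraries, a fit of only the groups compared, an absolute log2 fold change of at least 1, each library left out in turn and a block for the shared saline labels. Chosen after seeing the data were library totals without TMM factors, leaving out mitochondrially encoded genes or genes of chromosomes X and Y, and a term for LPS mice with label numbers below 200. Pseudocount alternatives planned for FPKM alone were not run, since the table holds counts.

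The edgeR and camera steps were tested on simulated counts drawn from the means, dispersions and library sizes of these data, 15703 genes with 100 changed 2-fold and 100 changed 4-fold. For knockout against wild type with LPS, 39% of the 2-fold and 88% of the 4-fold changes were called, with 11 false among 138 calls. With saline these were 30% and 90%, with 5 false among 125 calls. For LPS against saline they were 40% and 93% in wild type (7 false of 140) and 33% and 85% in knockout (4 false of 122). For the interaction they were 6% and 63% (3 false of 72), so changes of 2-fold were mostly below what this design can call there. Of 50 random lists of independently drawn genes at most 2 had an unadjusted camera p below 0.05 in any comparison. The simulation used 1 dispersion per gene for all groups and drew genes independently. Its shares therefore describe the fitted model, and may not hold for the LPS mice, which varied more than the saline mice. The data.table package, version 1.17.8, read the tables, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.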

Results

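RNA from kidneys of 13 mice was sequenced to ask how loss of DsbA-L, the mitochondrial and peroxisomal protein encoded by Gstk1, changed the kidney's transcript response to lipopolysaccharide (LPS), the bacterial cell-wall component used to provoke septic acute kidney injury. The mice formed 4 groups: wild type given saline (n = 3), knockout given saline (n = 3), wild type given LPS (n = 4) and knockout given LPS (n = 3). LPS was injected into the peritoneum at 10 mg/kg and saline in a volume of 200 µL. Each library held between 14372212 and 17668334 counts, and 15703 of 34745 genes were abundant enough to test. LPS libraries are named by the ends of their labels, AKI-317, AKI-319, AKI-12 and AKI-13 for wild type and AKI-320, AKI-156 and AKI-381 for knockout. Fold changes are log2 values ± SE from the edgeR model, and levels are CPM, counts scaled to a common library total with TMM factors, given as mean ± SD. P-values weigh a difference against a spread between mice that was estimated for each gene over all 13 libraries together. LPS mice varied more than saline mice, so p-values between LPS groups rest in part on the smaller saline spread. Those between saline groups rest in part on the larger LPS spread and may miss differences.

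The targeted gene matched the labels in every library. Gstk1 (ENSMUSG00000029864), a glutathione S-transferase of mitochondria and peroxisomes, is a protein-coding gene on the + strand of chromosome 6 from 42245935 to 42250447 (GRCm38). It stood at 48.9 ± 7.30 CPM in wild-type saline kidney and 2.97 ± 0.694 CPM in knockout saline kidney (n = 3 and 3). Under LPS it stood at 29.9 ± 9.68 CPM in wild type (n = 4) and 0.910 ± 0.774 CPM in knockout (n = 3). Wild-type libraries held 297 to 830 Gstk1 counts. Knockout saline libraries held 41 to 60, and knockout LPS libraries AKI-320, AKI-156 and AKI-381 held 27, 1 and 19. The knockout difference was -4.04 ± 0.48 with saline (edgeR adjusted p = 0.00601) and -5.0 ± 0.52 with LPS (edgeR adjusted p = 0.000784). Within the knockout, Gstk1 fell by 1.67 ± 0.53 with LPS, a call that ended without any 1 knockout saline library or knockout LPS library AKI-381. In wild type its change was -0.71 ± 0.38, which did not pass the test.

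Treatment and sex changed together. Xist, the RNA that silences 1 X chromosome in females, had 11446 to 19041 counts in each of the 6 saline libraries and at most 10 in each of the 7 LPS libraries. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d had 0 counts in every saline library and were present in every LPS library, where Ddx3y had 951 to 2996 counts. The saline mice were therefore female by these genes and the LPS mice male, so every LPS against saline value below is also male against female. The comparisons of knockout with wild type lay within 1 sex, female for saline and male for LPS.

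**Figure D1:**
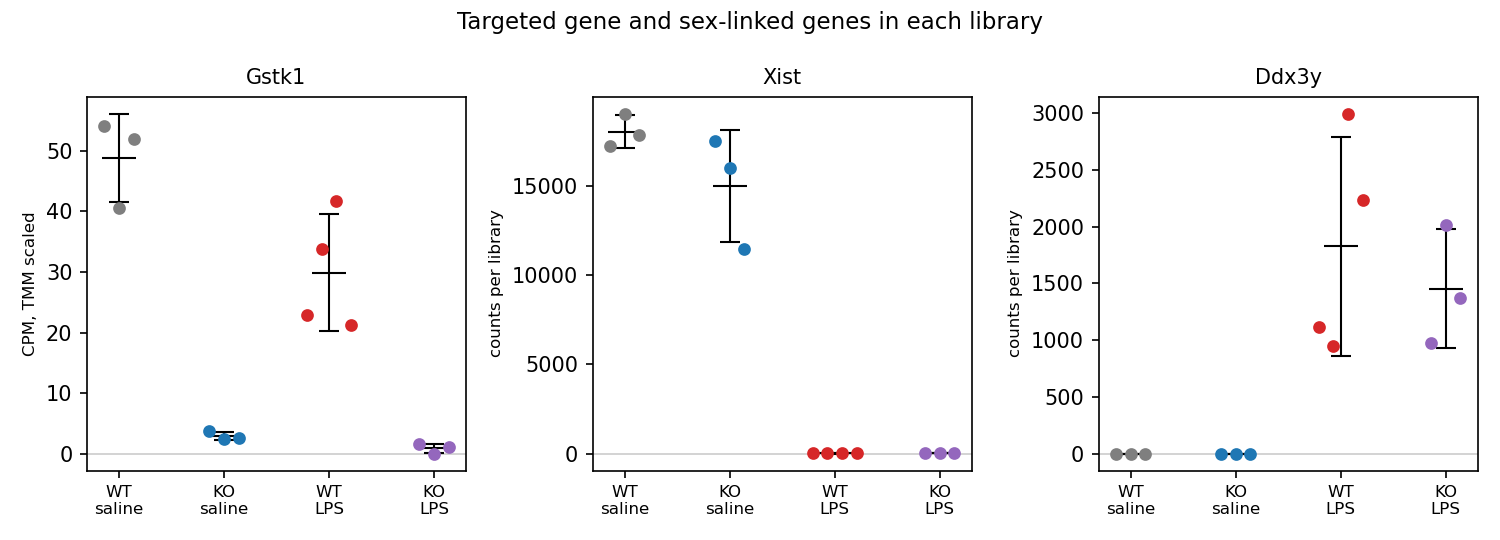
Gstk1 in CPM and Xist and Ddx3y in counts (y axes, linear) for each of the 13 libraries (points) by group (x axis), with bars at the group mean ± SD. Gstk1 was at or below 3.77 CPM in the 6 knockout libraries, and Xist and Ddx3y separated saline from LPS libraries without overlap.

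The first principal component of log2 CPM held 69.1% of the variance and followed treatment. Saline libraries lay between -94.2 and -82.8 on it, wild-type LPS libraries between 94.1 and 110.8, and knockout LPS libraries AKI-320 and AKI-381 between these, at 18.8 and 20.1. Knockout LPS library AKI-156 lay at 79.4, near wild type. Transcripts of mitochondrial DNA made up 18.9 ± 3.24% of counts in wild-type LPS kidney (n = 4) and 14.9 ± 2.03% in knockout LPS kidney (n = 3), against 21.7 ± 0.358% and 22.2 ± 0.365% with saline (n = 3 each).

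**Figure D2:**
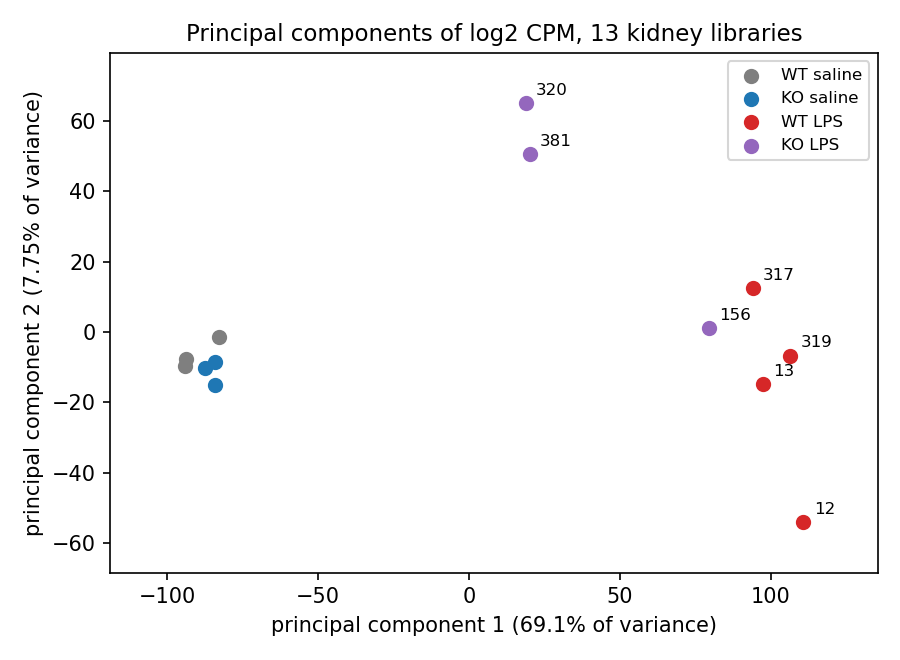
First (x axis) and second (y axis) principal components of log2 CPM over the tested genes, 1 point per library, coloured by group, with label numbers beside the LPS libraries. They hold 69.1% and 7.75% of the variance, and knockout LPS library AKI-156 lies at 79.4 on the first, beside the wild-type LPS libraries.

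In wild-type kidney, LPS was accompanied by a rise of acute-phase, cytokine, interferon and tubular injury transcripts and a fall of loop of Henle and distal tubule markers, lists that passed camera also with an estimated correlation (adjusted p between 0.0133 and 0.0413). Saa1, a serum amyloid A acute-phase protein, rose by 14.44 ± 0.74, Saa2, a near-identical paralog between which reads cannot be assigned with certainty, by 13.27 ± 0.63 and Orm2, an acute-phase carrier protein, by 12.69 ± 0.64 (n = 4 against 3). Lcn2, a tubular injury marker that binds bacterial siderophores, rose by 9.71 ± 0.46, from 5.47 ± 3.67 to 4619 ± 441 CPM. Il6, the pro-inflammatory cytokine, and Csf3, the granulocyte growth factor, had 0 counts with saline and were at least 1220-fold and 1170-fold higher with LPS, taking 3 counts over the saline group as the floor, a bound of 794-fold for Il6 without AKI-12. Fabp1, a fatty acid carrier, fell by 8.86 ± 0.63, Slc7a12, an amino acid transporter, by 8.52 ± 0.49 and Egf, the growth factor of the distal tubule, by 5.09 ± 0.47. Slc7a12 is among kidney genes known as female-biased, and the saline mice were female.

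Of 26 cytokine and chemokine genes tested, 26 rose, and so did 34 of 34 interferon-stimulated genes, 20 of 21 acute-phase and complement genes and 20 of 21 tubular injury markers. Adjusted over the list alone, these counts were the same. Examples are Cxcl9, a T-cell chemokine (7.96 ± 0.65), Lif, a cytokine of the interleukin-6 family (7.06 ± 0.43), Gbp2, an interferon-induced GTPase (8.88 ± 0.47), and Irf7, a transcription factor of the interferon response (5.52 ± 0.25). Among 23 NF-kB genes 18 rose (20 adjusted over the list alone), with Nfkbiz at 4.32 ± 0.31 and Nfkbia, the NF-kB inhibitor, at 2.79 ± 0.19. These 5 lists were higher than other genes by camera, also with an estimated correlation, at adjusted p between 0.0133 and 0.0413. In 22 AP-1 and immediate-early genes 19 rose and 1 fell (also adjusted over the list alone), among them Maff (4.09 ± 0.30), Junb (3.31 ± 0.29) and Fosl2 (2.33 ± 0.21), with camera adjusted p = 0.0797 with an estimated correlation. This list, called the AP-1 list or AP-1 genes for short, also holds genes that are not AP-1 subunits, such as Egr1, Ier3, Dusp1 and Zfp36. Of 18 M1-type macrophage markers 17 rose (18 adjusted over the list alone, camera adjusted p = 0.0797 with an estimated correlation), including Nos2, the inducible nitric oxide synthase, by 7.19 ± 0.55. All 12 neutrophil markers tested, of 18 listed, rose (12 adjusted over the list alone, camera adjusted p = 0.145 with an estimated correlation). Of 30 cytokine and chemokine genes listed, 26 were tested. Genes near 0 with saline pass the filter only through the LPS libraries, so that all tested members rose is in part due to the filter.

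Among 24 proximal tubule markers 18 fell and 4 rose with LPS in wild type, with Lrp2 and Cubn, the endocytic receptors megalin and cubilin, at -3.37 ± 0.24 and -3.73 ± 0.34 (camera adjusted p = 0.145 with an estimated correlation). Of 15 loop of Henle and distal tubule markers 12 fell (camera adjusted p = 0.0322 with an estimated correlation), and 13 did when adjusted over the list alone. The fatty acid oxidation list had 18 members that fell and 3 that rose of 25, led by Cyp4a14 (-5.53 ± 0.36) and Acaa2 (-2.99 ± 0.20), with camera adjusted p = 0.0653 with an estimated correlation. Of 12 podocyte markers 10 fell (camera adjusted p = 0.173 with an estimated correlation), as did 9 of 15 endothelial markers (10 adjusted over the list alone, camera adjusted p = 0.277 with an estimated correlation), while 3 endothelial markers rose, a count of 0 without wild-type saline N2 and of 1 without wild-type saline N1 or N3, AKI-12 or AKI-13. Tek, the endothelial angiopoietin receptor, fell by 3.18 ± 0.25. Of 9 adipose markers 6 also fell (7 adjusted over the list alone, camera adjusted p = 0.595 with an estimated correlation). Their levels varied between saline mice, with Adipoq, a hormone of fat cells, at 8.02, 37.2 and 39.8 CPM in the wild-type saline libraries and 0.22 to 2.51 CPM in the wild-type LPS libraries. The proximal tubule and fatty acid oxidation counts were the same adjusted over the list alone, and so was the podocyte count. Across all genes, 4458 rose and 4496 fell at edgeR adjusted p below 0.05, of 15703 tested.

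In knockout kidney 2310 genes were higher and 2024 lower with LPS (edgeR, n = 3 against 3). Saa1 rose by 11.83 ± 0.66, Lcn2 by 9.48 ± 0.46 and Havcr1, the tubular injury marker Kim-1, by 9.80 ± 1.33, while Egf fell by 5.64 ± 0.54 and Bhmt, an enzyme of homocysteine remethylation, by 6.82 ± 0.73. Saa2 had 3 counts over the knockout saline libraries and was 10600-fold higher with LPS (counting interval 3640 to 51500). Il6 was at least 112-fold higher and Cxcl5, a neutrophil-attracting chemokine, at least 665-fold higher, both from 0 counts. Without AKI-156 these bounds were 30.7-fold and 356-fold. The counting interval and the bounds cover counting error only.

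All 21 acute-phase genes, 31 of 34 interferon-stimulated genes, 20 of 21 injury markers, 20 of 26 cytokines and 16 of 23 NF-kB genes rose in the knockout, with camera adjusted p between 0.00438 and 0.0251 with an estimated correlation. Adjusted over the list alone the counts were 21, 31, 20, 23 and 18. Of 22 AP-1 and immediate-early genes 8 rose (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.299 with an estimated correlation). Fos and Jun, the founding subunits of AP-1, stood at -0.85 ± 0.46 and 0.79 ± 0.29 without passing the test. Among proximal tubule markers 18 of 24 fell and 1 rose (20 and 2 adjusted over the list alone, camera adjusted p = 0.0274 with an estimated correlation), led by Slc34a1, the phosphate transporter, at -3.11 ± 0.31. Of 25 oxidative phosphorylation subunits 17 fell (20 adjusted over the list alone, camera adjusted p = 0.152 with an estimated correlation). Of 14 fibroblast, mesangial and pericyte markers 6 rose and 1 fell, with Col3a1 and Col1a1, fibrillar collagens, at 3.01 ± 0.36 and 2.81 ± 0.47 (6 and 2 adjusted over the list alone, camera adjusted p = 0.243 with an estimated correlation). Among the smaller counts, 2 proximal tubule markers rose without knockout AKI-381 or wild-type AKI-12, 2 fibroblast markers fell without knockout AKI-320 or wild-type AKI-12 or AKI-319, and 2 AP-1 genes fell without knockout saline N3. With library totals in place of TMM factors, 3150 genes were higher and 1341 lower in this comparison, 70.1% higher against 53.3%, as the median of all genes moved by 0.168.

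The comparison of knockout with wild type under LPS addresses whether loss of DsbA-L altered the injury response, and it lay within male mice. Nos2 stood at 134 ± 60.5 CPM in wild type and 8.59 ± 5.48 CPM in knockout (n = 4 and 3), a difference of -3.96 ± 0.44 (edgeR adjusted p = 0.000908). Lif differed by -2.66 ± 0.31 (edgeR adjusted p = 0.000908), the chemokine Cxcl10 by -3.35 ± 0.54 and Irg1, the enzyme of itaconate synthesis in macrophages, by -4.65 ± 0.63. Lcn2 (-0.29 ± 0.30) and Havcr1 (-0.52 ± 0.83) did not pass the test. Havcr1 stood at 1020 to 1560 CPM in wild type and 773 to 1050 CPM in knockout under LPS. Its spread was estimated over all 13 libraries, including wild-type saline N2 at 33.7 CPM against 0.978 and 0.541 in N1 and N3. Its SE may therefore be too large for the LPS mice, and the missing call does not show equal levels. Higher in the knockout were Col1a1 (3.03 ± 0.43), Abca9 (4.77 ± 0.74) and Abca8a (3.81 ± 0.61), which encode lipid transporters of the ABCA family, and Rhcg, an ammonia channel of the collecting duct (3.25 ± 0.51). Among knockout LPS libraries each of these was lowest in AKI-156. Rhcg stood at 5.78 CPM there, against 59.5 in AKI-320, 40.6 in AKI-381 and 2.79 to 4.78 in wild type.

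Of the 26 cytokine and chemokine genes 13 were lower in the knockout and 0 higher (edgeR), and 20 were lower when adjusted over the list alone. Il6 stood at 80.6 ± 62.0 CPM in wild type and 7.26 ± 9.33 CPM in knockout, a difference of -3.48 ± 0.94. Tnf differed by -2.84 ± 0.62, the neutrophil chemokine Cxcl2 by -3.14 ± 0.59 and Ccl2, the monocyte chemoattractant, by -1.69 ± 0.43, while Il1b at -2.48 ± 0.85 did not pass. The cytokine list had camera adjusted p = 0.113 with an estimated correlation. Of 34 interferon-stimulated genes 26 were lower (27 adjusted over the list alone, camera adjusted p = 0.133 with an estimated correlation), with the antiviral GTPase Mx1 at -3.49 ± 0.54, the peptide transporter Tap1 at -1.71 ± 0.24 and Gbp5 at -2.65 ± 0.41. Of 18 M1-type macrophage markers 12 were lower (15 adjusted over the list alone, camera adjusted p = 0.133 with an estimated correlation). Of 18 M2-type markers 3 were lower and 1 was higher (the same adjusted over the list alone), and with library totals 1 was lower and 3 were higher. The higher gene was Mrc1, the mannose receptor, at 1.2 ± 0.27, and Arg1 stood at 0.52 ± 0.66 without passing. Without knockout AKI-381 and without knockout AKI-320, the lower counts were 4 and 6 for cytokines, 6 and 8 for interferon-stimulated genes, 3 and 5 for M1-type markers and 0 and 0 for M2-type markers. The M2-type count was 1 lower without wild-type AKI-319 and 2 higher and 4 lower without knockout AKI-156.

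Both transcription factor families named in the study's title had lower members in the knockout. Among 23 NF-kB genes 12 were lower and 0 higher (edgeR, 15 lower adjusted over the list alone), with Rela, the p65 subunit, at -1.30 ± 0.25, Nfkb1 at -0.68 ± 0.17, Nfkbiz at -1.28 ± 0.26 and Nfkbia at -0.96 ± 0.18 (camera adjusted p = 0.066 with an estimated correlation). Among 22 AP-1 and immediate-early genes 15 were lower (1 higher and 15 lower adjusted over the list alone), with the AP-1 subunit Junb at -1.37 ± 0.26 (camera adjusted p = 0.113 with an estimated correlation). Egr1 at -2.01 ± 0.32 and Ier3 at -2.23 ± 0.37 were also lower, but are immediate-early genes outside AP-1. Fos at -1.44 ± 0.44 and Jun at -0.99 ± 0.28 also passed, but library totals in place of TMM factors ended both calls and that of Nfkb1, with adjusted p of 0.0745, 0.0516 and 0.109 by edgeR. Without knockout AKI-381 and without AKI-320, 3 and 5 NF-kB genes and 7 and 9 AP-1 genes were lower. Fos passed narrowly, since its call ended in 11 of 24 alternatives, with adjusted p from 0.00751 to 0.193 over them by edgeR, DESeq2 and limma-voom.

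Some markers of resident cell types were higher in the knockout. Of 20 macrophage and monocyte markers 7 were higher and 2 lower (the same adjusted over the list alone, camera adjusted p = 0.133 with an estimated correlation), among them Cx3cr1, the fractalkine receptor (4.09 ± 0.60), C1qa (1.58 ± 0.27) and Adgre1, the F4/80 antigen (2.06 ± 0.44). Of 15 endothelial markers 7 were higher and 2 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.288 with an estimated correlation), including Tek (1.98 ± 0.25), Plvap (1.59 ± 0.24) and Pecam1 (1.06 ± 0.16). Of 15 endothelial activation and coagulation genes 7 were lower and 1 higher (9 and 1 adjusted over the list alone, camera adjusted p = 0.109 with an estimated correlation), led by F3, tissue factor, at -2.57 ± 0.40. Of 14 fibroblast, mesangial and pericyte markers 5 were higher (5 adjusted over the list alone, camera adjusted p = 0.205 with an estimated correlation), as were 4 of 12 podocyte markers (6 adjusted over the list alone, camera adjusted p = 0.288 with an estimated correlation). None of 12 neutrophil markers passed edgeR's threshold, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 and limma-voom, but 3 were lower without knockout AKI-156. S100a9, a calcium-binding protein of neutrophils, stood at 0.11 ± 0.71, with 121 CPM in AKI-156 against 17.6 and 11.9 in knockout AKI-320 and AKI-381. Without AKI-381 and without AKI-320, higher markers numbered 5 and 6 for macrophages, 3 and 3 for endothelium and 2 and 1 for podocytes, and 2 and 3 endothelial activation genes were lower, while 7 podocyte markers were higher without AKI-156. With 1 library left out, the lower endothelial and macrophage markers and the higher activation gene ranged from 0 to the counts given.

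Of 15 loop of Henle and distal tubule markers 6 were higher in the knockout (9 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.362 with an estimated correlation), including Kcnj1, the ROMK potassium channel (2.19 ± 0.40), and Tmem52b (2.25 ± 0.34). Of 24 proximal tubule markers 8 were lower and 1 higher (11 and 3 adjusted over the list alone, camera adjusted p = 0.406 with an estimated correlation), including Slc34a1 (-1.52 ± 0.28) and Miox, an inositol-degrading enzyme (-1.88 ± 0.35), and with library totals the split was 6 lower and 5 higher. Of 15 collecting duct markers 4 were higher and 2 lower (5 and 3 adjusted over the list alone), with Atp6v1b1, a proton pump subunit, at 1.75 ± 0.40. Foxi1, among the lower ones, did not pass with library totals (edgeR adjusted p = 0.127). Of 21 injury markers 7 were lower, Hbegf (-1.12 ± 0.19) and Gdf15 (-1.69 ± 0.45) among them (9 adjusted over the list alone, camera adjusted p = 0.288 with an estimated correlation). Among 21 antioxidant genes 7 were lower and 1 higher (8 and 1 adjusted over the list alone, camera adjusted p = 0.135 with an estimated correlation), the mitochondrial dismutase Sod2 at -1.13 ± 0.19. Over single libraries left out, 3 to 9 loop and distal markers were higher, 3 to 11 proximal markers lower and 0 to 6 higher, 0 to 6 collecting duct markers higher, 1 to 11 injury markers lower and 1 to 10 antioxidant genes lower. Without knockout AKI-381 and without AKI-320 these were 3 and 3, 3 and 5, 0 and 0, 1 and 0, 1 and 1, and 1 and 1, and wild-type AKI-319 also took the loop count to 3, the collecting duct and injury counts to 2 and the antioxidant count to 4. Most of the highest counts came without knockout AKI-156, and that of 11 proximal markers without wild-type AKI-13, while wild-type AKI-317 left 3 loop and 4 injury markers, and AKI-12 or AKI-13 2 collecting duct markers.

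**Figure D3:**
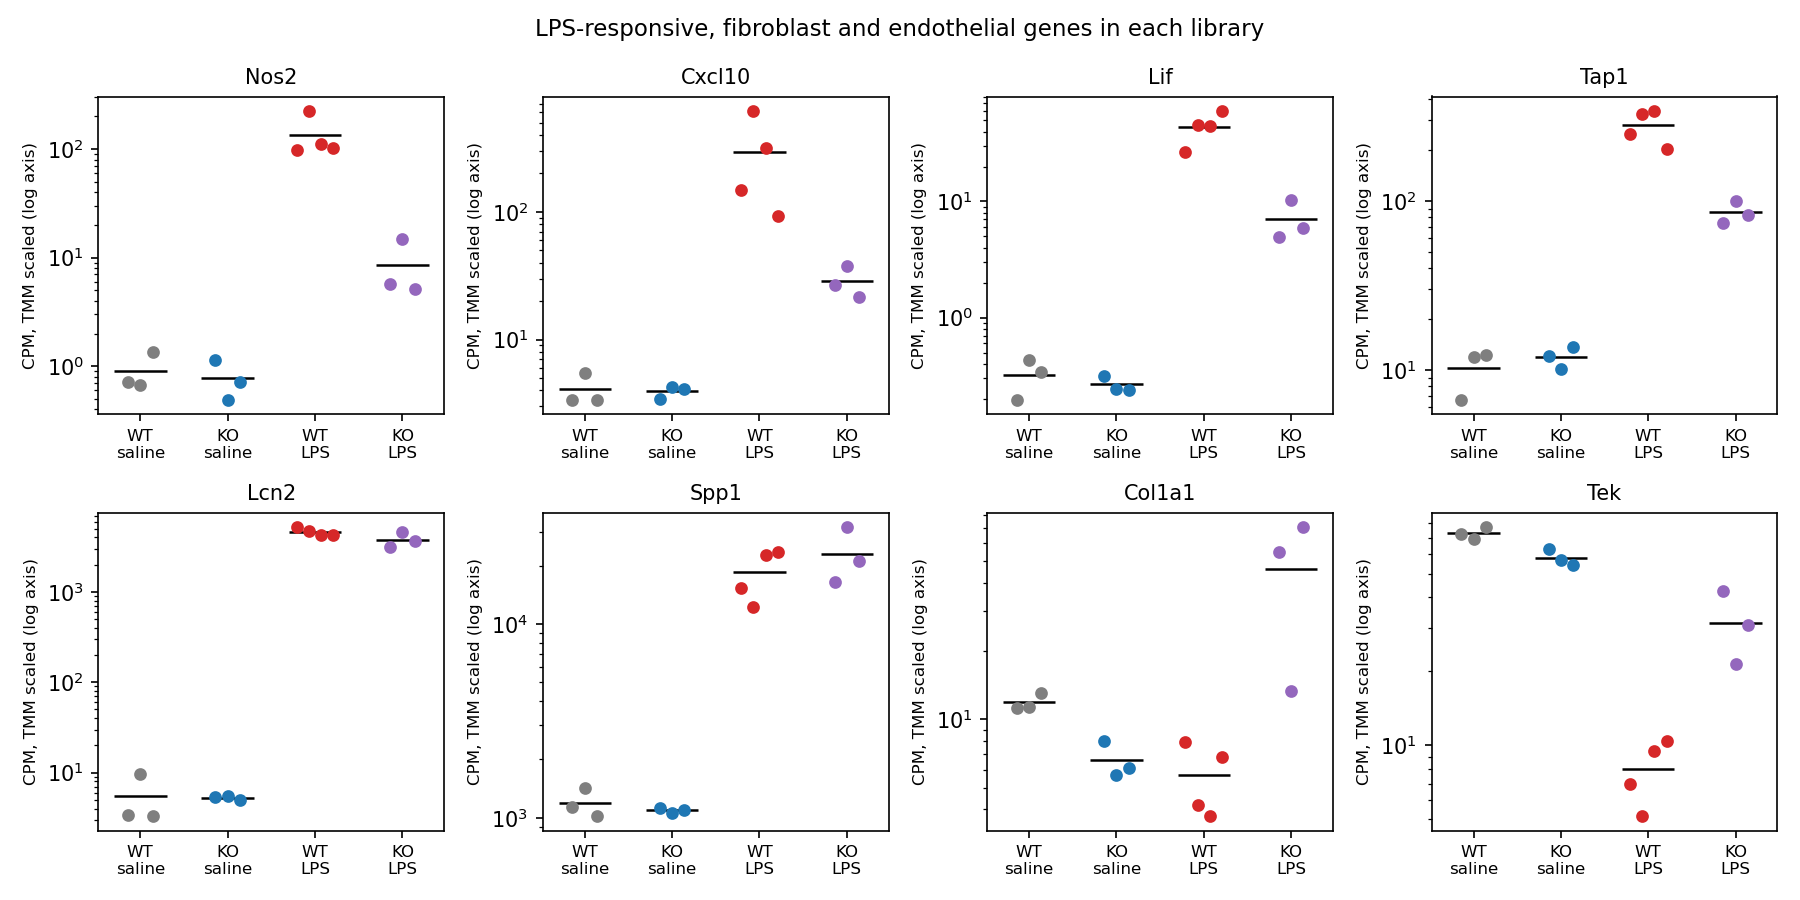
CPM (y axes, log scale) of 8 genes in each of the 13 libraries (points) by group (x axis), with lines at the group mean. Nos2, Cxcl10, Lif and Tap1 were lower in knockout than wild-type LPS kidney, Col1a1 and Tek were higher, and Lcn2 (-0.29 ± 0.30) did not differ by more than the test's threshold.

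Of the 34 lists, 17 passed camera with the preset correlation and 0 with an estimated one in this comparison. In all, 1373 genes were higher and 988 lower in knockout than wild type under LPS (edgeR adjusted p below 0.05), and 2858 genes, 18.2% of those tested, had levels that did not overlap between the groups, where chance alone gives 5.71%. The spread between LPS mice was larger than between saline mice, and a fit of the 7 LPS libraries alone called 48 higher and 54 lower, while the calls of Il6, Tnf, Ccl2, Fos, Jun and Nfkb1 ended both without knockout AKI-320 and without AKI-381, and that of Il6 also without wild-type AKI-319, AKI-12 or AKI-13. Counts moved to 348 and 172 without knockout AKI-381, 479 and 253 without AKI-320, 2434 and 2105 without AKI-156 and 835 and 576 without wild-type AKI-319, and library totals in place of TMM factors gave 3323 and 477, 87.4% higher against 58.2%, as the median of all genes moved by 0.339. DESeq2 called 1757 higher and 1638 lower, and a term for label numbers below 200, chosen after the data were seen, gave 1690 and 1610.

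With saline, in female mice, edgeR called 1 gene higher and 2 lower in knockout than wild-type kidney, with 582 genes at an unadjusted p under 0.05. Levels did not overlap between the groups for 3125 genes, 19.9% of those tested, where chance alone gives 10%. Gstk1 was 1 of the lower genes. The other was Dtx4, an E3 ubiquitin ligase of the Deltex family, at -1.53 ± 0.19 (edgeR adjusted p = 0.00601, n = 3 and 3). The higher gene was Ciart, a repressor of the circadian clock, at 2.91 ± 0.31 (edgeR adjusted p = 0.00397), from 1.44 ± 0.251 to 10.9 ± 2.0 CPM. Of 17 clock genes 1 was called, and 6 were higher and 3 lower when adjusted over the list alone (camera adjusted p = 1.93e-05 with the preset correlation, adjusted p = 0.179 with an estimated correlation). Dbp, a clock output transcription factor, and Arntl, the clock activator Bmal1, chosen after their values were seen, stood at 1.90 ± 0.35 and -1.76 ± 0.36 without passing over all genes. No gene of the cytokine, NF-kB or AP-1 lists passed edgeR's threshold with saline, where 0, 1 and 2 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0. Nfkbia stood at 0.67 ± 0.19. Levels of Nfkbia, Nfkbiz, Junb, Egr1 and Zfp36 were higher in every knockout than in any wild-type saline library, while those of Rela, Nfkb1, Fos and Jun overlapped. The edgeR p-values here rest in part on the larger spread of LPS mice, so a shift in these lists without LPS is not excluded. Of the 34 lists, 12 passed camera with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.179). With the preset correlation the fibroblast (camera adjusted p = 1.93e-05), endoplasmic reticulum stress (5.13e-05), adipose, heat shock, M2-type and injury lists were lower, and the clock, AP-1 (0.00501), glucocorticoid, lymphocyte, macrophage and interferon lists higher. DESeq2 called 11 genes higher and 14 lower, a fit of the 6 saline libraries alone 5 and 4, and edgeR 0 lower without knockout saline N2 or N3, where adjusted p of Gstk1 reached 0.0937, the highest over its 24 alternatives.

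The difference of the 2 LPS responses, which also sets male against female knockout differences, was tested as an interaction. It was positive for 213 genes and negative for 117 (edgeR, 3487 genes at an unadjusted p under 0.05). Nos2 rose with LPS by 7.19 ± 0.55 in wild type and 3.45 ± 0.52 in knockout, a difference of -3.74 ± 0.75. The differences for the chemokine Cxcl10 (-3.29 ± 0.76) and Cd274, the checkpoint ligand PD-L1 (-2.85 ± 0.63), were also negative. Abca9 (5.47 ± 0.92), Col1a1 (3.87 ± 0.63) and Cx3cr1 (4.25 ± 0.78) had positive differences. Of 22 AP-1 and immediate-early genes 8 were negative (13 adjusted over the list alone). Among them were Fos at -2.77 ± 0.65 and Zfp36, not an AP-1 subunit but a protein that destabilises cytokine transcripts, at -2.14 ± 0.28. Of 34 interferon-stimulated genes 6 were negative (26 adjusted over the list alone), and of 23 NF-kB genes 3 were (9 adjusted over the list alone), with Nfkbia at -1.63 ± 0.26. Camera adjusted p with an estimated correlation was 0.113 for the AP-1, 0.147 for the interferon and 0.0907 for the NF-kB list. Without knockout AKI-156 the negative genes of these lists numbered 13, 24 and 9, without AKI-320 or AKI-381 1, 0 and 1, without wild-type AKI-319 3, 0 and 1, and without any 1 saline library at most 2, 0 and 1, while the interferon count was 1 without wild-type AKI-12 and 10 without AKI-13. Leaving out any 1 saline library, or knockout LPS library AKI-320 or AKI-381, left 5 to 20 positive and 5 to 20 negative genes and ended most of these calls, against 1414 and 1115 without knockout AKI-156 and 27 and 19 without wild-type AKI-319. DESeq2 called 783 and 602, limma-voom 65 and 58, and library totals gave 801 and 94, 89.5% positive against 64.5%, as the median moved by 0.365. A term for LPS mice with label numbers below 200, chosen after the data were seen, gave 574 and 503.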

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

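The tests of sex, scaling, the response as a whole, library AKI-156 and the other splits of the samples were chosen only after the results were seen. The term for label numbers was also added then, with its prediction written before its value was known.

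The LPS response differed between genotypes for 44 of the genes named in the text, by a test of the difference itself (edgeR interaction, adjusted p below 0.05), 17 with a positive and 27 with a negative difference in log2 units. The comparison also sets males against females, as above. Without any 1 saline library, or without knockout LPS library AKI-320 or AKI-381, 5 to 20 genes in each direction were called in all, and without wild-type LPS library AKI-319 27 and 19. Genes were in part named because they passed this same test, by size or within fixed lists, many of them inflammatory, so the number 44 and the make-up follow from the naming rule, and no list passed camera for this difference with an estimated correlation (smallest adjusted p = 0.0907). Inflammatory and early-response genes with a negative difference were Nos2 (-3.74), Sectm1b (-3.37), Cxcl10 (-3.29), Cd274 (-2.85), Ier3 (-2.84), Fos (-2.77), Egr1 (-2.69), Gbp5 (-2.62), F3 (-2.33), Zfp36 (-2.14), Tap1 (-1.92), Junb (-1.86), Nfkbiz (-1.82), Plaur (-1.79), Nfkbia (-1.63), Maff (-1.61), Dusp1 (-1.47), Hbegf (-1.24) and Sod2 (-1.15), of which Hbegf (-0.863) and Sod2 (-0.805) did not pass with library totals. Clock genes with a negative difference were Ciart (-3.67) and Per1 (-1.92). Part of such a difference can lie in the saline libraries. Ciart stood at 1.24 to 1.72 CPM in wild type and 8.95 to 12.9 CPM in knockout with saline, and at 3.96 to 4.86 and 1.48 to 3.17 CPM with LPS. Per1 and Nfkbia were also higher in knockout with saline, at 71.3 to 97.7 against 34.1 to 45 CPM and 37.7 to 42.4 against 23.2 to 26.6 CPM. So were Zfp36 (67.2 to 102 against 47.7 to 54.2 CPM), Egr1 (25.2 to 36.6 against 16.6 to 21.6), Junb (17.8 to 21.2 against 12.8 to 15.6), Nfkbiz (16.6 to 18.4 against 11.8 to 12.3) and Sectm1b (15.7 to 20.3 against 12.5 to 14.2). Levels of the other inflammatory and early-response genes listed overlapped between the saline groups. With saline, 19.9% of all tested genes did not overlap. Tubular and metabolic genes with a negative difference were Slc6a19os (-4.89), an antisense gene and so uncertain, Mfsd2a (-4.39), a lipid transporter, Upp2 (-3.25), a uridine phosphorylase, Eif4ebp3 (-2.90), the organic anion transporter gene Slc22a7 (-2.05) and the androgen-regulated Kap (-2.03). Of these, Slc6a19os, Mfsd2a, Upp2 and Eif4ebp3 were higher in every knockout than in any wild-type saline library, while Slc22a7 and Kap overlapped.

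Positive differences were found for the lipid transporter genes Abca9 (5.47) and Abca8a (4.35), for the collagens Col1a1 (3.87), Col3a1 (2.66) and Col1a2 (2.44), and for Cx3cr1 (4.25) of resident macrophages and Tek (2.31) of endothelium. In tubule genes they were Rhcg (3.42), Kcnj1 (2.50), Tmem52b (2.31), Ranbp3l (2.93) and Cyp4a14 (2.48), a fatty acid hydroxylase. The others were Kcnip2 (4.63), Wscd2 (3.76), Crocc (3.73), Mtfp1 (3.52), which acts in mitochondrial fission, and Dtx4 (2.19). Dtx4 was also lower in knockout with saline, at 8.46 to 9.61 CPM against 20.5 to 32.7 CPM in wild type. So were Abca9 (6.86 to 10.7 against 13.2 to 15.5 CPM), Col1a1 (5.7 to 8.04 against 11.2 to 13.1) and Crocc (33.9 to 46.1 against 56.6 to 60.1). Col3a1, Tek, Kcnj1 and Wscd2 were also lower in every knockout than in any wild-type saline library, while the other genes of this paragraph overlapped.

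In wild-type LPS kidney, the group of 4 libraries, 7 of 146 values tested had 1 library far from the other 3, and chance alone gives about 1 in 20. Library AKI-319 was highest for Nos2 (224 CPM against 98.5 to 111), Plaur (110 against 61.8 to 69.3), Cubn (63.2 against 35.2 to 37.5) and Xist (0.683 against 0.143 to 0.195). Library AKI-13 was highest for Ugt1a2 (9.08 against 0.304 to 0.456), whose reads are shared with overlapping family members, and lowest for Cxcl5 (108 against 170 to 178). Library AKI-12 was highest for Eif2s3y (122 against 79.7 to 81.5).

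The first pattern weighed is the sex of the mice. Y-linked genes had counts in 7 of 7 LPS libraries and 0 of 6 saline libraries, so for LPS against saline sex and treatment cannot be told apart, because no library joins male with saline or female with LPS. Of 12 kidney genes known as male-biased the median difference was 1.92 in wild type and 0.877 in knockout, and of 5 known as female-biased it was -4.80 and -3.05, which is consistent with part of these calls coming from sex. Among the 5 were Slc7a12 (-8.52 in wild type) and Cyp4a14 (-5.53), named above as falls with LPS. Among the 12 were Kap (1.91), Slc22a30 (1.88) and Slc7a13 (5.39), proximal tubule markers that rose in wild type. Between knockout and wild-type LPS mice, all male, edgeR called 4 of the 12 lower and 1 higher, and 3 of the 5 higher and 1 lower, so some of these genes also changed where sex did not. An effect of LPS stays open as the explanation the design names.

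The second pattern is the lower level of inflammatory genes in knockout LPS kidney, 73 of 116 tested members of the cytokine, NF-kB, AP-1, M1-type and interferon lists lower and 0 higher by edgeR, with a median of -1.28 and camera adjusted p between 0.066 and 0.133 with an estimated correlation (22 lower without knockout AKI-381, 31 without AKI-320 and 14 in a fit of LPS libraries alone). Scaling is unlikely as the whole cause, since the median was -0.92 with library totals, where all genes moved by 0.339, and a difference between low and high label numbers is too, since 98.6% of the 73 stayed lower with a term for it. A smaller LPS response over many genes was consistent with the data, as differences between genotypes ran against the wild-type response with r across genes of -0.53 in the split of wild-type LPS libraries nearest 0 and -0.685 in the split farthest from it, over 6 splits, although genes are not independent replicates. With all 4 shared libraries r was -0.728 and the covariance -0.825, where 20 simulations with neither an LPS nor a genotype effect gave -0.436 and -0.057, a covariance difference of -0.768. The simulations used 1 dispersion per gene for all groups. They gauge only what sharing libraries gives by itself, at a spread that may be too small for LPS mice. A response smaller by the same share in every list was not seen with TMM factors, as interaction medians were -0.0629 in acute-phase genes, -0.517 in proximal tubule markers and -0.348 in oxidative phosphorylation subunits beside wild-type medians of 4.77, -1.26 and -0.305 (library totals moved the interaction median of all genes by 0.365). The acute-phase median may depend on AKI-156, since without it 11 of 21 acute-phase genes were lower in knockout than wild type under LPS. Loss of DsbA-L, a different dose reached or another stage of illness, each of which may give a smaller response, were not separated here.

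The third pattern is knockout LPS library AKI-156, whose nearest library was wild-type LPS library AKI-13 (r across genes of 0.9751), whereas knockout libraries AKI-320 and AKI-381 were nearest each other (0.9677). A wild-type mouse or wild-type RNA in it is unlikely, since its 1 Gstk1 count, with an upper 95% counting limit of 5.57, allows a wild-type share of at most 1.2%. Its library size of 15336685 counts lay within the range of the other LPS libraries, 14372212 to 17668334, which argues against size. Along the wild-type LPS response it scored 0.805, against 0.499 and 0.504 for the other knockout libraries and 0.912 to 1.01 for wild type. AKI-156 also shares a label number below 200 with wild-type AKI-12 and AKI-13, and edgeR called 3577 genes for a term for such numbers. The meaning of the numbers is not given, and whether this grouping accounts for AKI-156 was not tested. No biological explanation was tested.

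Other splits of the same libraries were counted for each comparison. For LPS against saline in wild type, 8954 genes were called and at most 4110 in the others of 35 splits, so chance is unlikely to give as many. For the interaction, 330 genes were called against at most 8 in the others of 100 splits drawn. Chance is unlikely there too, but only part of the possible splits was drawn. That count also fell to 5 to 20 genes in each direction without any 1 saline library, AKI-320 or AKI-381. For knockout against wild type under LPS chance stays open, since 2 of 35 splits called as many as the real 2361. The other, of libraries AKI-12, AKI-13 and AKI-156 against AKI-317, AKI-319, AKI-320 and AKI-381, called 2594. That split points to a structure of the samples, and it parts low from high label numbers, whose meaning the labels do not give. With a term for low label numbers, chosen after this split was seen, 1690 genes were higher and 1610 lower in knockout. For LPS against saline in knockout (4334 genes, at most 0 in the others) and for knockout against wild type with saline (3 genes, at most 1), the 10 splits are too few for a share below 0.05.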

How the results depend on the processing

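Library totals, the term for label numbers and the removal of mitochondrial or X and Y genes were chosen only after the data were seen. RLE factors, both filter alternatives and those removals kept every count of called genes within 1.5 times. Of 615 values of named genes, 614 kept direction and side of the threshold with RLE factors, 600 of 610 with DESeq2, 578 with limma-voom, 581 with library totals and 606 without a filter. Fitting only the groups compared kept 407 of 502 and lost 94. Leaving out a library kept between 509 (knockout LPS AKI-381) and 606 (wild-type LPS AKI-13).

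An absolute log2 fold change of at least 1 gave, by its stricter rule, 2739 genes higher with LPS in wild type, 1414 higher and 1329 lower in knockout, and 871 higher and 515 lower in knockout than wild type under LPS. Library totals gave 1341 lower with LPS in knockout, 3323 higher and 477 lower between genotypes under LPS, and 801 positive for the interaction. The median of all genes moved with them by -0.196 for LPS in wild type, 0.168 for LPS in knockout, 0.339 between genotypes under LPS, -0.0266 with saline and 0.365 for the interaction. DESeq2 called 1638 lower between genotypes under LPS, 11 higher and 14 lower with saline, and 783 and 602 for the interaction, where limma-voom called 65 and 58. The term for label numbers gave 1610 lower between genotypes under LPS and 574 and 503 for the interaction. For library totals, the other tools and the term the cause was not tested. Fits of only the groups compared gave 48 and 54 under LPS, and 5 and 4 with saline, each from its own spread and fewer samples.

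With 1 library left out, between genotypes under LPS 348 to 2434 genes were higher and 172 to 2105 lower, with saline 1 to 2 and 0 to 2, and for the interaction 5 to 1414 positive and 5 to 1115 negative. The lowest counts under LPS came without knockout AKI-381 and the highest without knockout AKI-156. Ngp, a neutrophil granule gene at 0.30 and not called in knockout against wild type under LPS, stood at -1.80 without knockout AKI-156 (edgeR adjusted p = 0.0424, the lowest of a range up to 1) and at 0.866 without wild-type AKI-12, and the cause was not tested.

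The saline libraries share the labels N1, N2 and N3 between genotypes. With these as a replicate block, edgeR called 0 genes higher and 1 lower. Same-number correlations of deviations from the group means were 0.0179, -0.0501 and -0.0299, so no pairing by number was seen. Such correlations cannot show that the mice were unpaired. Libraries held 14372212 to 17668334 counts, and no fit at another depth was run, so what depth limits was not tested.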

Other observations

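The response score, the window around Gstk1 and the single-library values given here were chosen only after the data were seen, while the gene lists were not. Some genes of DNA sensing, Toll-like receptor signalling, cell death and stress were lower in knockout than wild-type kidney under LPS. Of 10 genes of the cGAS-STING pathway, which senses cytosolic DNA, 4 were lower and 0 higher by edgeR (4 adjusted over the list alone, camera adjusted p = 0.288 with an estimated correlation), among them Ifi205 at -2.51 ± 0.61 and the exonuclease gene Trex1 at -1.82 ± 0.54, and with library totals 2 were lower and 1 higher and Trex1 did not pass. Of 21 Toll-like receptor signalling genes 4 were lower, including Tlr2 (-1.59 ± 0.33) and Cd14, the LPS co-receptor (-1.86 ± 0.41), and 1 was higher (8 and 2 adjusted over the list alone, camera adjusted p = 0.407 with an estimated correlation), a split of 2 lower and 3 higher with library totals. Of 21 regulated cell death genes 4 were lower and 0 higher (7 lower adjusted over the list alone, camera adjusted p = 0.135 with an estimated correlation), with Mlkl and Ripk3, which carry out necroptosis, at -0.98 ± 0.20 and -1.19 ± 0.31, and with library totals 2 were lower and 0 higher and Ripk3 did not pass. Of 11 glucocorticoid-responsive genes 5 were lower (5 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.37 with an estimated correlation), Dusp1 at -1.07 ± 0.23 among them, against 3 lower and 3 higher with library totals. Of 10 heat shock genes 3 were lower (3 adjusted over the list alone, camera adjusted p = 0.462 with an estimated correlation), with Hspa8 at -0.86 ± 0.21. Hspb1 and Bag3 were also lower, but did not pass with library totals (edgeR adjusted p = 0.107 and 0.365). With saline, too, Hspa8 was lower in knockout, at 696 to 807 CPM against 1080 to 1630 CPM in wild type, so its difference was not limited to LPS. In the endoplasmic reticulum stress list 2 of 19 were lower, with the transcription factor Xbp1 at -1.49 ± 0.29, and 1 was higher (3 and 1 adjusted over the list alone, camera adjusted p = 0.869 with an estimated correlation), and library totals gave 1 lower and 5 higher. Without knockout AKI-381, 0 genes of the cGAS-STING, Toll-like, cell death, glucocorticoid and heat shock lists were lower by edgeR, and without AKI-320 these were 1, 2, 1, 0 and 0. Without wild-type AKI-319 they were 2, 3, 2, 1 and 1. Leaving out single saline libraries took the glucocorticoid count to 3 and the heat shock count to as low as 1, and over single libraries left out 1 to 5 endoplasmic reticulum stress genes were lower and 0 to 3 higher, 0 without wild-type AKI-319 or AKI-12 or knockout AKI-320 or AKI-381 and 3 without wild-type AKI-13. The higher Toll-like gene was called by edgeR without wild-type saline N1 or knockout AKI-156, but not without any other single library.

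In the same comparison, of 25 fatty acid oxidation genes 5 were higher and 3 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.533 with an estimated correlation), with Cyp4a14 at 2.56 ± 0.32 and the coactivator Ppargc1a at 1.39 ± 0.28, and library totals gave 13 higher and 2 lower. Of 25 oxidative phosphorylation subunits 1 was lower (0 adjusted over the list alone, 8 at an unadjusted p under 0.05, 4 by DESeq2 and 1 by limma-voom, camera adjusted p = 0.462 with an estimated correlation). This gene, Cox4i1, did not pass with library totals (edgeR adjusted p = 0.249). In the glutathione S-transferase family, Gstk1 was the 1 member of 21 that edgeR called lower, while DESeq2 called 2 lower, and Gstm4 (1.14 ± 0.29) and Gstt3 (0.98 ± 0.27) were higher by edgeR (the same adjusted over the list alone, camera adjusted p = 0.987 with an estimated correlation), with reads of near-identical members uncertain. Of 17 clock genes 2 were higher and 3 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.533 with an estimated correlation), led by Hlf at 1.65 ± 0.24, and library totals gave 3 higher and 0 lower. Over single libraries left out, 2 to 7 fatty acid oxidation genes were higher and 0 to 4 lower, 0 to 4 oxidative phosphorylation subunits lower, 0 to 4 glutathione S-transferases higher, and 1 to 3 clock genes higher and 0 to 6 lower. Without knockout AKI-381 and without AKI-320, 2 and 3 fatty acid oxidation genes and 0 and 0 glutathione S-transferases were higher, and without AKI-156 7 and 4 were.

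None of 21 acute-phase and complement genes was called by edgeR (3 at an unadjusted p under 0.05, 1 by DESeq2 and 1 by limma-voom), nor any of 19 cell cycle genes (1 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom). Without knockout AKI-156, however, 11 acute-phase genes were lower and 1 cell cycle gene and 1 adipose marker higher by edgeR, and without wild-type AKI-319 1 acute-phase gene was lower. Of 11 lymphocyte and NK cell markers Il7r was lower (-1.59 ± 0.50, not passing over the list alone). Of 10 platelet and red cell markers Slc4a1, an anion exchanger of red cells and of the collecting duct, was higher (3.39 ± 0.84, also adjusted over the list alone). Both calls ended without AKI-320 and without AKI-381, and that of Il7r also without most other single libraries and with library totals. None of 9 adipose markers (2 at an unadjusted p under 0.05), 4 adrenal, pancreas, liver and muscle markers (0) or 5 sex-linked genes (0) was called by edgeR, DESeq2 or limma-voom. With saline the adipose list was lower in knockout by camera at the preset correlation (camera adjusted p = 6e-07), but not with an estimated one (adjusted p = 0.244), and Adipoq at -1.94 ± 0.998 did not pass edgeR's threshold.

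A score of each LPS library along the wild-type LPS response, built without that library, was 0.603 ± 0.175 (SD, n = 3) in knockout and 0.959 ± 0.0465 (SD, n = 4) in wild type. The axis was built from 1 of the groups compared, so no p is given. Wild-type and knockout responses, which share no library, correlated at r = 0.842 across genes, which are not independent replicates. Both responses hold the change of sex.

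Within 10 Mb of Gstk1, where DNA of the strain used for targeting can remain, 21 of 141 other tested genes were called between genotypes under LPS, 14.9% against 15% elsewhere. With saline 0 of 141 were called by edgeR. Havcr1 stood at 33.7 CPM in wild-type saline library N2 against 0.978 and 0.541 in N1 and N3. Cyp27b1, the renal enzyme that activates vitamin D, stood at 262 CPM in knockout LPS library AKI-381 against 38.0 and 30.8 in AKI-320 and AKI-156. Dbp stood at 89.0, 57.0 and 102 CPM in the knockout saline libraries against 14.7, 37.3 and 14.4 in wild type, and the hour of sampling was not given in the sources used here.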
